A study of Mus musculus with 6 samples.

How the data were processed

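Messenger RNA was sequenced from 6 libraries of mouse T helper 17 (TH17) cells, a CD4 T cell subset that makes interleukin-17. Per the labels' protocols, naive CD4 T cells were polarised with IL-1β, IL-23, IL-6 and TGF-β in medium whose only added sugar was 10 mM glucose or 10 mM galactose, and were used on day 5. Poly(A) RNA was selected and the library kit keeps the strand, per the labels' protocols, whereas the strand setting of the counting is not given in the sources used here. The submitters' processing notes name bcl2fastq, Trimmomatic 0.39, STAR 2.5.2a, RSEM 1.3.1 and the mouse builds mm10 and GRCm38, without saying which step used which. Group and replicate were taken from the sample titles, 3 libraries per sugar.

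The authors deposited, per the file headers, RSEM expected counts for 55450 genes in each library, which estimate reads per gene by sharing out reads that match several genes and need not be whole. The same deposited tables give TPM, transcript abundance corrected for length and scaled to the same total in each library, and for 141767 transcripts an isoform percent, the share of the gene's abundance given to each transcript. A series table whose name says counts was found to hold TPM, since its 55450 rows equal the TPM of the library tables within 0.01 in each library, so it was used for that check only. All 55450 gene identifiers matched GENCODE mouse release 21 on GRCm38, which gave coordinates, gene types and exonic overlaps.

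Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, the default expression filter, the robust quasi-likelihood fit and Benjamini-Hochberg adjustment, with a threshold of 0.05. The filter left 13762 genes. Levels are CPM, counts scaled to a common library total with TMM factors, given as mean ± SD with n = 3 per group, and log2 fold changes are galactose over glucose with a standard error (SE). Gm42418 levels are CPM of all counts, without TMM factors. Lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01 between genes, over the 28 lists with at least 5 tested members, and again with an estimated correlation and with fry. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and plots.

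Depth ranged from 27003955 to 44763067 expected counts per library, and the common biological coefficient of variation was 8.28%. The fit was tested on simulated counts for this comparison, with 13762 genes of which 200 were changed, in 5 draws per fold. With each gene's own estimated dispersion, it recovered 27.3% of genes changed 1.25-fold, 71.3% at 1.5-fold and 85.2% at 2-fold. False calls then made up 10.2%, 8% and 7.1% of the calls, above the nominal 5%. Counts drawn from a smooth dispersion trend gave 5%, 6% and 4.2%, so the excess went with dispersions that varied from gene to gene. The limits this test had to meet were revised after its first results were seen. The data gave 7683 calls among 13762 genes, against 200 changed genes in the simulation. Simulated counts also had the same dispersion in both sugars and no library that stood apart. In the data, the lowest Pearson correlation between libraries on log2 CPM was 0.9953 within glucose and 0.9868 within galactose. Galactose replicates 1 and 3 gave 0.994. The recovery and false-call shares therefore need not carry over to the data. Adjusted p-values close to 0.05 should still be read with caution.

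The main design, the lists and most alternatives were fixed before the data were examined. Named genes followed a fixed rule. It always took a short set that includes Bcl2l1, Bcl2l11, Il17a and Foxp3. It added the 5 largest increases and 5 largest decreases among changed genes with at least 5 CPM in the higher group, non-overlapping groups and a symbol that is no gene model or clone. It then took the 2 members with the smallest p of each primary list, 1 of each secondary list, and the most abundant member of each list for another cell type, which gave 50 genes, some of which are not reported here. Other list members quoted as examples were picked after their values were seen.

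Alternatives at the gene level were 12 planned ones, covering scaling, tool, unit, filter, fold threshold, test and replicate block, plus 6 fits that each left out 1 library. Another 2 were added after seeing the data, namely leaving out structural RNA genes and a fold threshold of 2. Structural RNA genes were chosen by gene type, plus a few by symbol, among them Gm42418 and Lars2. DESeq2 1.42.0, limma-voom and limma-trend on log2(TPM + 1) and log2(TPM + 0.1) were among the planned ones. DESeq2 gave no adjusted p for 10 genes. After seeing the data, 12 gene families were also defined by symbol pattern, along with a list of IL-2 and STAT5 induced genes written down before its values were seen.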

Results

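The data comprise 6 RNA-seq libraries of mouse TH17 cells, 3 cultured in glucose and 3 in galactose. Galactose enters glycolysis slowly, and the series describes the galactose cells as relying on oxidative phosphorylation (OXPHOS) and the glucose cells as glycolytic. Its title names resistance to apoptosis and persistence as the subjects of interest. Total expected counts were 44763067, 37154380 and 41092321 in glucose replicates 1 to 3, and 41814350, 27003955 and 29119734 in galactose replicates 1 to 3. The labels do not say that the replicates came from separate mice or cultures, so p-values measure only the spread between these samples, which may be technical.

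Galactose-cultured cells had 13.0-fold more Foxp3 transcript, which encodes the lineage factor of regulatory T cells, and less of many TH1, cytotoxic and memory-associated transcripts. The level of Foxp3 was 14.3 ± 1.65 CPM in glucose and 186 ± 9.17 CPM in galactose (SD, n = 3 each). Transcripts for Bcl2 and Bcl2l1, which encode survival proteins, rose, while Bcl2l11, which encodes the death-promoting protein BIM, fell. Of 10 anti-apoptotic genes 2 rose and 6 fell, and of 24 pro-apoptotic genes 10 rose and 9 fell. Neither list passed camera. Genes of the MYC and ribosome biogenesis list rose together (camera adjusted p = 1.39e-13, or 0.126 with an estimated correlation). The TH17 regulator gene Rora fell. In all, 7683 of 13762 tested genes (55.8%) changed by the edgeR quasi-likelihood test, 3724 higher and 3959 lower in galactose. The estimated fold exceeded 2 for 568 of the higher and 875 of the lower genes. Groups did not overlap for 8634 genes (62.7%), against 10% by chance. On log2(TPM + 1), 20% of the calls were higher, against 48.5% with TMM-scaled counts, and the median of all genes moved by -0.17 on the log2 scale. The TPM fits applied no TMM factors, which were lower in the galactose libraries.

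**Figure D1:**
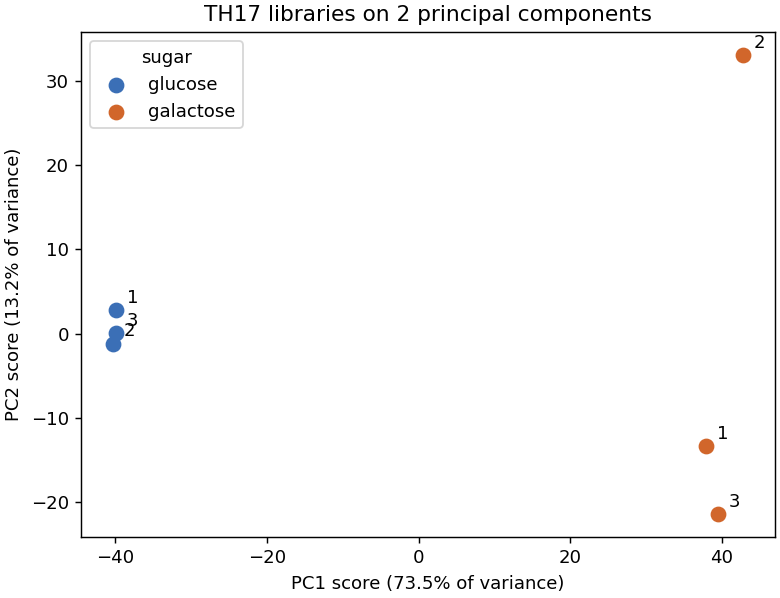
Scores of the 6 libraries on the first 2 principal components of log2 CPM, coloured by sugar and numbered by replicate. PC1 (73.5% of the variance) separates the sugars, and PC2 (13.2%) sets galactose replicate 2, at 33.06, apart from the other galactose libraries, at -13.31 and -21.38.

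Galactose replicate 2 stood apart in composition. Gm42418, a gene model at a ribosomal RNA repeat, took 8.66% of its counts. In CPM without TMM factors, that is 36.2 times the mean of the other 5 libraries. Protein-coding genes took 88.7% of its counts, compared with 97.1% to 97.3% elsewhere. Counts of list members that moved by over 1.5 times without this library are given below with the value without it.

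The largest increases under the naming rule were in Il9, Foxp3, Actr3b, Gpr83 and Alox15. Il9, which encodes a cytokine of TH9 and mast cell biology, had 599 counts over the galactose libraries and 2 over the glucose libraries, a ratio of 414 with an exact 95% interval of 114 to 3420 that covers counting error only. Gpr83, a receptor gene known from regulatory T cells, rose from 7.36 ± 0.209 to 60.2 ± 4.20 CPM. Actr3b rose by 3.35 ± 0.137 (SE) and Alox15, a lipoxygenase gene, by 3.00 ± 0.117 on the log2 scale. The largest decreases were in Ly6g, Ifitm1, Cyp4f39, Filip1 and Gpr141. Ly6g fell from 44.2 ± 0.707 to 1.28 ± 0.101 CPM, and the interferon-inducible Ifitm1 from 270 ± 7.55 to 12.3 ± 2.21 CPM. Ly6g and Ifitm1 belong to families of similar genes, between which the counting could split reads. Cyp4f39 fell by 4.16, Filip1 by 3.92 and Gpr141 by 3.84 on the log2 scale.

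**Figure D2:**
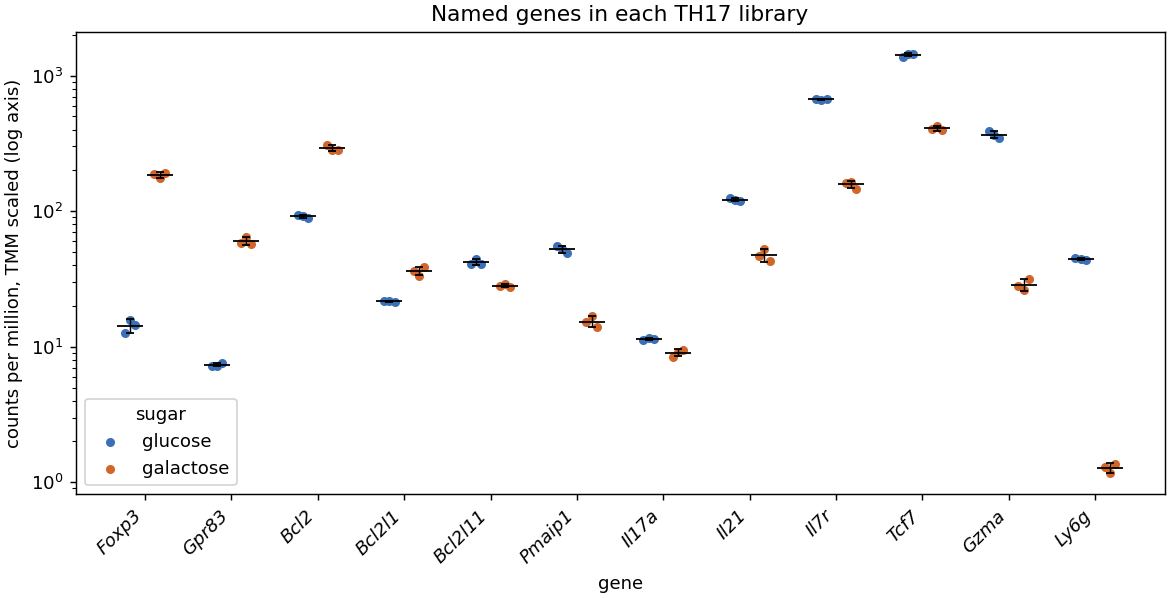
Expression of 12 named genes in each library, in TMM-scaled CPM on a log axis, with glucose and galactose side by side. Points are libraries, and black bars give the mean and SD of 3 libraries. Foxp3 lies between 175 and 193 CPM in the galactose libraries and between 12.6 and 15.8 CPM in the glucose libraries.

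Apoptosis genes moved in both directions. Bcl2 (chromosome 1, 106538178 to 106714274, GRCm38) rose from 91.5 ± 1.88 to 291 ± 14.99 CPM, a log2 change of 1.67 ± 0.0501 (SE, edgeR adjusted p = 5.66e-10). Bcl2l1, which encodes BCL-XL (ENSMUSG00000007659.18, chromosome 2, 152780668 to 152831728), rose from 21.6 ± 0.108 to 36.1 ± 2.59 CPM (log2 0.74 ± 0.0647, edgeR adjusted p = 1.94e-06). Bcl2l11 (ENSMUSG00000027381.16, chromosome 2, 128126038 to 128162547) fell from 42.1 ± 2.18 to 28.2 ± 0.734 CPM (log2 -0.58 ± 0.0607, edgeR adjusted p = 8.46e-06). The other 6 anti-apoptotic genes that passed fell, among them Birc3 (-0.60) and Mcl1 (-0.21), so 2 of 10 rose and 6 fell. Of 24 pro-apoptotic genes, 10 rose and 9 fell, and on log2(TPM + 1) the count of higher genes was 5 and the list median turned from 0.11 to -0.10, or 0.07 relative to all genes. Pmaip1, which encodes NOXA, fell by 1.77 and Bmf by 1.39 on the log2 scale, while Bid rose by 1.21 and Diablo by 0.95. Exons of Bid overlap the opposite-strand gene Bcl2l13 over 17.7% of their length. Neither list passed camera (adjusted p = 0.807 and 0.772), and for both, the median and mean or test differed in sign.

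The TH17 list was lower in galactose, with 11 of 17 members down and 3 up (camera adjusted p = 0.00134; adjusted p = 0.126 with an estimated correlation). Il17a (ENSMUSG00000025929.4, chromosome 1, 20730905 to 20734496) fell from 11.4 ± 0.220 to 9.02 ± 0.539 CPM (log2 -0.34 ± 0.0775, edgeR adjusted p = 0.00272). Il21 fell by 1.36, Il23r by 1.22 and Il1r1, an IL-1 receptor gene, by 2.69 on the log2 scale. The members that rose were Ccr6 (1.05), Stat3 (0.45) and Tmem176a (0.43), of which 1 passed on log2(TPM + 1).

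TH1 genes were lower, with 8 of 10 members down (camera adjusted p = 1.18e-12; adjusted p = 0.0611 with an estimated correlation). Ifng, which encodes interferon-γ, fell by 2.43 on the log2 scale, whereas Ccl5 rose by 1.05. Of 15 genes of naive, memory and stem-like T cells, 12 fell and 2 rose (camera adjusted p = 1.03e-08; adjusted p = 0.119 with an estimated correlation). Il7r, the IL-7 receptor gene, fell from 671 ± 5.71 to 158 ± 9.82 CPM, Tcf7 from 1423 ± 38.7 to 409 ± 15.9 CPM, and Bcl6 by 2.26 on the log2 scale, while Foxp1 rose by 0.79 and Ccr7 by 0.24. Genes of the inhibitory receptor and exhaustion list were lower in 7 of 14 cases (camera adjusted p = 0.00618; adjusted p = 0.168 with an estimated correlation), including the transcription factor gene Tox2 (-1.12) and the receptor gene Tigit (-1.72), and 1 was higher, or 3 without galactose replicate 2. TH2 genes split, with 2 up and 2 down of 6, and Ccr4 rose by 1.24 (camera adjusted p = 0.171).

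Regulatory T cell genes moved apart, with 7 of 12 up and 5 down, and passed as higher (camera adjusted p = 0.00216; adjusted p = 0.151 with an estimated correlation). Foxp3 (ENSMUSG00000039521.13, chromosome X, 7573644 to 7595245) and Gpr83 led the increases, by 3.70 and 3.03 on the log2 scale against a list median of 0.62. Whether the list would pass as higher without these genes was not tested. Foxp3 shares 18.6% of its exon length with the same-strand gene Flicr. Il2ra, which encodes CD25, rose by 0.70. Ctla4 fell by 1.02, Ikzf2 by 0.89, Itgae by 0.81, Il10 by 0.54 and Nrp1 by 0.52 on the log2 scale. Markers of other cell types moved beside these groups. Of 10 cytotoxic T and NK cell markers, 8 fell (camera adjusted p = 8.92e-06; adjusted p = 0.168 with an estimated correlation) and Gzma, the most abundant, went from 366 ± 20.96 to 28.7 ± 2.84 CPM; with no low-count filter, 2 of the markers were also higher. Of 11 B cell markers, 7 rose and 3 fell, with Ighm the most abundant at 807 ± 10.0 and 454 ± 17.8 CPM (camera adjusted p = 0.171). On log2(TPM + 1) 4 B cell markers rose, and with at least 5 CPM in 3 libraries 1 did and the list median turned from positive to -0.90. Myeloid markers fell in 3 of 9 cases, or 5 without galactose replicate 2, with Itgam highest at 4.07 CPM in glucose (camera adjusted p = 0.339). Of the erythroid markers, 2 were tested and neither passed, with Hbb-bt at 2.43 and 2.59 CPM.

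All 18 tested members of the MYC and ribosome biogenesis list were higher, with a median log2 change of 0.74. The list passed camera at the preset correlation (adjusted p = 1.39e-13) but not with an estimated one (camera adjusted p = 0.126). Rrp12 rose from 46.3 ± 1.80 to 100.7 ± 2.78 CPM, and Myc itself by 0.62 on the log2 scale. Cell cycle genes rose in 19 of 25 cases and fell in none past the threshold, or rose in 9 on log2(TPM + 1) (camera adjusted p = 6.73e-05; adjusted p = 0.126 with an estimated correlation). The replication helicase genes Mcm2 to Mcm7 were among them, with Mcm4 up by 0.76, while Mki67 stood at -0.06. Genes of the ATF4 and amino acid stress response rose in 13 of 23 cases and fell in 4, or 14 and 4 adjusted over the list alone (camera adjusted p = 0.0111; adjusted p = 0.291 with an estimated correlation). Phgdh of serine synthesis rose by 1.14 and the amino acid transporter gene Slc7a5 by 0.89, whereas of the list's transcription factor genes, Atf4, Atf3 and Ddit3 fell by 0.60, 0.89 and 0.65, and Atf5 and Cebpb rose by 0.30 and 0.57. Interferon response genes rose in 13 of 17 cases and fell in 3 (camera adjusted p = 0.0116; adjusted p = 0.333 with an estimated correlation), Ifit3 by 0.91, and this call was lost with at least 5 CPM in 3 libraries (camera adjusted p = 0.0522). On log2(TPM + 1) the interferon counts were 6 higher and 4 lower.

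None of the energy metabolism lists passed camera in the main design. Of 75 nuclear-encoded OXPHOS subunits, 10 rose and 3 fell, or 7 and 1 adjusted over the list alone, with a median log2 change of 0.01 (camera adjusted p = 0.692, or 0.0551 without galactose replicate 2). The other 62 did not pass the gene threshold, which 55.8% of all tested genes did. Atp5b of ATP synthase rose from 947 ± 9.88 to 1323 ± 45.2 CPM. The counts depended on single libraries, with 32 higher and 2 lower without galactose replicate 2, 10 lower without galactose replicate 3, 6 higher and 1 lower without glucose replicate 2, and 1 lower without glucose replicate 1 or galactose replicate 1. On log2(TPM + 1) they were 3 higher and 29 lower, with a median of -0.06 relative to all genes, and with no low-count filter 6 were lower. Of 13 mitochondrially encoded subunits, 6 rose, or 5 adjusted over the list alone and 2 without glucose replicate 3, among them mt-Nd2 (0.36) and mt-Nd5 (0.36), and none passed on log2(TPM + 1), where the median turned from 0.17 to -0.01, or 0.16 relative to all genes (camera adjusted p = 0.345).

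Glycolysis genes rose in 15 of 22 cases and fell in 3, or 4 and 3 on log2(TPM + 1), and the list did not pass (camera adjusted p = 0.0922, or 0.018 without galactose replicate 2, 0.0433 without galactose replicate 1 and 0.0234 with no low-count filter). Hk2, a hexokinase gene, rose by 0.73 and Ldha by 0.67, while the glucose transporter gene Slc2a3 fell by 0.86. Of 14 galactose and pentose phosphate enzyme genes, 6 rose and 2 fell, or 1 and 4 on log2(TPM + 1), with the galactokinase gene Galk1 up by 0.74 and the mutarotase gene Galm down by 0.93 (camera adjusted p = 0.339). TCA cycle genes rose in 9 of 18 cases and fell in 2, and on log2(TPM + 1) 3 rose and 5 fell and the median turned from 0.16 to -0.05, or 0.12 relative to all genes. That list missed the threshold (camera adjusted p = 0.0602) and passed without galactose replicate 1 (0.0218) or galactose replicate 3 (0.0488) and with no low-count filter (0.012). Fatty acid oxidation genes rose in 4 and fell in 6 of 16 cases, or 0 and 10 on log2(TPM + 1), with Cpt1a down by 1.12 (camera adjusted p = 0.171).

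None of the remaining lists passed camera, and members past the threshold moved both ways in all of them but mitochondrial biogenesis. Of 28 sterol and fatty acid synthesis genes 13 rose and 8 fell (camera adjusted p = 0.339), and of 19 HIF-1 targets 6 rose and 6 fell (0.85), with Egln1 up by 0.41. For the HIF-1 targets the median and mean lay below 0 and the test's direction was up. Of 22 autophagy genes, 3 rose and 9 fell (camera adjusted p = 0.646), Phb2 by 0.48 and Bnip3l by -0.52. Of 16 p53 targets, 9 rose and 5 fell, or 10 and 5 adjusted over the list alone (camera adjusted p = 0.334). Antioxidant genes gave 5 up and 4 down of 14, or 3 up without glucose replicate 3 (camera adjusted p = 0.519), with Sod2 up by 0.78. ER chaperone genes gave 6 up and 5 down of 17 (camera adjusted p = 0.437), with Pdia4 up by 0.78. Mitochondrial biogenesis genes rose in 4 of 13 cases, Pprc1 by 0.53, or in 2 adjusted over the list alone, and in 2 when any single glucose replicate or galactose replicate 1 was left out (camera adjusted p = 0.437). On log2(TPM + 1) the higher genes fell to 3 for sterol synthesis, 1 for HIF-1 targets, 2 for antioxidants, 1 for ER chaperones and 0 for mitochondrial biogenesis, where 3 were lower, and the medians of all but the HIF-1 targets turned negative. Relative to all genes, they were 0.07 for sterol synthesis, -0.05 for antioxidants, 0.01 for ER chaperones and 0.08 for mitochondrial biogenesis. Counts adjusted over the list alone equalled those given for the other lists, except that 1 cytotoxic marker was then higher.

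**Figure D3:**
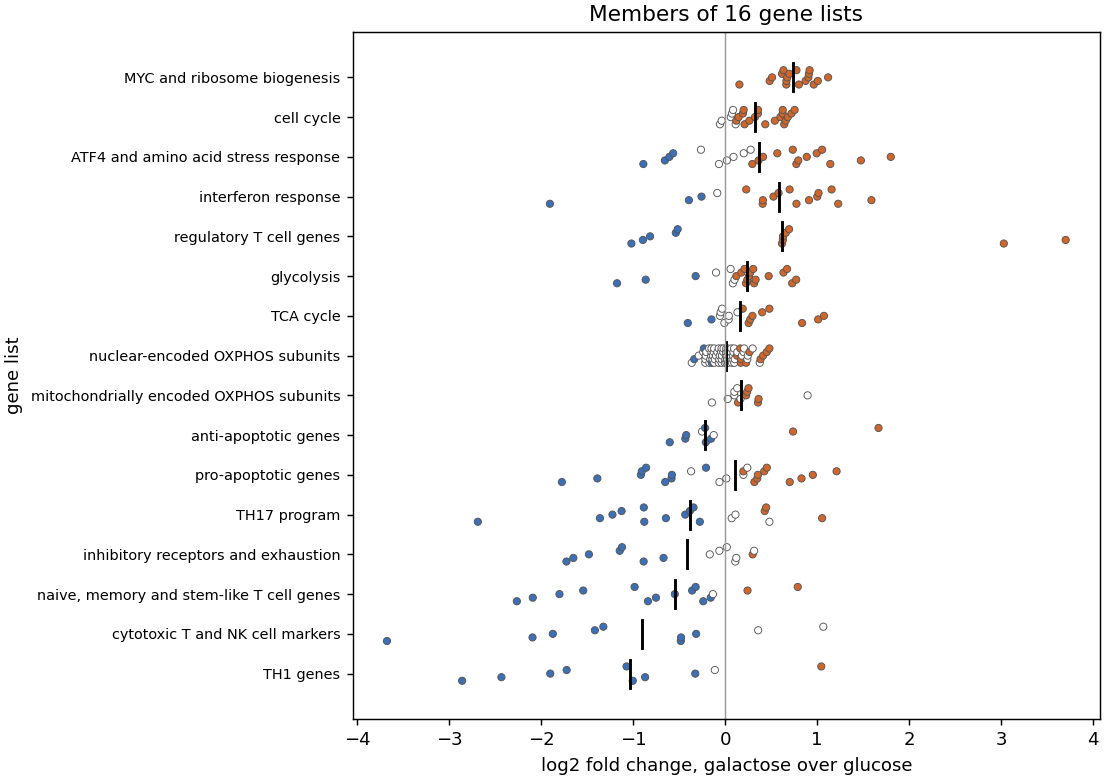
Log2 fold change, galactose over glucose, of each tested member of 16 gene lists. Filled points passed the edgeR threshold (orange higher, blue lower), open points did not, and black bars are list medians. All 18 members of the MYC and ribosome biogenesis list lie above 0, and 8 of 10 TH1 members are filled blue.

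Of 28 lists, 10 passed camera, 5 higher and 5 lower, and 0 passed with an estimated correlation, where 8 had an unadjusted p under 0.05. Groupings of the same libraries that mixed the sugars also gave list calls with the preset correlation, between 3 and 9 of them. Each such grouping held unequal numbers of the sugars on its sides, so part of the sugar difference stayed in the comparison. These counts therefore cannot show how many lists chance alone would call.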

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

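The tests on galactose replicate 2 were chosen after that pattern was seen. The isoform shares below come from transcript values of the same libraries, which the comparisons did not use. They drew attention because their groups lay at least 15 points apart. This held for 3 of 26443 transcripts of genes at 20 TPM or more in both groups. Groups did not overlap by any margin for 3391 of these transcripts.

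The transcript Wars-205 held 36.34 ± 1.2% of the abundance of Wars, a tryptophanyl-tRNA synthetase gene, in glucose and 13.22 ± 1.59% in galactose (SD, n = 3 each), with Wars-201 moving from 59.17% to 80.76%. Tnfrsf13b-203 held 0.77 ± 0.13% of Tnfrsf13b in glucose and 22.88 ± 2.86% in galactose. Such shares are RSEM estimates and were not tested.

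Genes grouped here as structural RNA took a large share of galactose replicate 2, where Gm42418 reached 86560 CPM (without TMM factors) and Lars2 0.698% of counts. Both were placed in this group by symbol, not by gene type. Lower depth is argued against, because galactose replicate 3, next in depth, held 0.923 times the Gm42418 CPM of replicate 1, also without TMM factors. Galactose culture as such is also argued against, since replicates 1 and 3 averaged 0.668 times the glucose mean, again without TMM factors. RNA without poly(A) tails remains a candidate explanation: 48 small-RNA and histone genes had a median log2 of 1.984 in this library over the other galactose libraries, compared with 0.004 for other protein-coding genes. The 12 small-RNA genes (median 4.947) in part restate the pattern. The 36 histone genes alone had a median of 1.163 with quartiles of 0.076 and 2.171. The explanation therefore stays open, as does why such RNA would have entered this library. This library also differed in genes outside these sets. Of 80 cytosolic ribosomal protein genes, 29 were called higher in galactose with this library and 74 without it.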

How the results depend on the processing

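The 2-fold threshold and the removal of structural RNA genes were added after seeing the data. No called gene named under the rule changed direction under these alternatives, whereas several list medians and member counts turned on log2(TPM + 1), which moved the median of all genes by -0.17. Relative to all genes, the medians that turned stayed above 0 except those of nuclear-encoded OXPHOS subunits (-0.06) and antioxidants (-0.05). Counts of changed genes kept within 1.5 times of 7683 under the alternatives other than fold thresholds, from 6143 with at least 5 CPM in 3 libraries to 8212 with no filter, and from 6609 to 8512 on leaving out 1 library, the highest without galactose replicate 2, with 7416 genes shared. Requiring a fold above 1.5 left 1721 genes, 709 higher and 1012 lower, and above 2 left 618, 222 higher and 396 lower, as a stricter question must. On log2(TPM + 1) and log2(TPM + 0.1), 1244 and 1272 genes were higher, and mt-Nd2, mt-Nd5, Egln1, Pprc1 and Itgam lost their calls. The TPM fits applied no TMM factors, which were 1.048 to 1.056 in glucose and 0.92 to 0.98 in galactose. Leaving them out lowers galactose relative to glucose, the direction in which the median moved. How many of the lost calls follow from this was not tested. The list count was 0 with an estimated correlation and 23 with fry, which does not compare a list with other genes. The replicate numbers did not pair the libraries (correlations of deviations -0.014, -0.064 and 0.01), and the replicate block gave 7335 genes and moved the TCA cycle list from adjusted p = 0.0602 to 0.0466 (camera range over its alternatives 0.012 to 0.519; fry, a different test, 0.0048). With no low-count filter, glycolysis (0.0234) and the TCA cycle (0.012) also passed camera. Of 10 splits of the 6 libraries, too few for a share under 0.1, the real one gave 7683 genes and the highest other 0. The other splits gave up to 189 genes at an unadjusted p under 0.05. No split but the real one reached the real count. Every other split mixed the sugars on both sides, so the sugar difference added to the spread within each side. Few gene calls were therefore likely in those splits, and their gene counts do not show what chance alone would give. For lists the real split gave 10 and the highest other 9, the lowest 3. The other splits kept part of the sugar difference, so their list counts do not show what chance alone would give. At this depth 13762 of 55450 genes had enough counts to be tested. With 200 genes changed, 27.3% of the smallest simulated changes were recovered, a share that need not carry over to the data. The part of depth in that recovery was not tested.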

Other observations

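The gene families here were 12 in number and, like the tests of Igkc, of galactose replicate 2 for the B cell markers and of regulatory T cell share, were chosen after the data were seen. The tests of the MHC class II genes and of the STAT5 list were written before their values were.

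Granzyme genes, which encode killing proteases, fell in 8 of 9 cases and rose in 1 (camera adjusted p = 1.28e-12; adjusted p = 0.0758 with an estimated correlation), with Gzmb down from 530 to 79.0 CPM; with at least 5 CPM in 3 libraries, 4 fell. Interleukin receptor genes fell in 15 and rose in 4 of 25 cases (2.86e-06; adjusted p = 0.0758 with an estimated correlation), and chemokine receptor genes fell in 9 and rose in 5 of 14 (0.000172; adjusted p = 0.0758 with an estimated correlation), Ccr2 by -3.17, with 3 rising on log2(TPM + 1) or at 5 CPM. GIMAP GTPase genes fell in 6 of 8 cases (4.57e-06; adjusted p = 0.0762 with an estimated correlation) and V-ATPase subunit genes in 8 of 16 (0.00381; adjusted p = 0.0762 with an estimated correlation), Atp6v0d2 by -3.46.

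Cytosolic ribosomal protein genes rose in 29 of 80 cases, in 74 without galactose replicate 2 and in 7 on log2(TPM + 1) (camera adjusted p = 0.00355; adjusted p = 0.835 with an estimated correlation). Aminoacyl-tRNA synthetase genes rose in 14 of 20 cases and fell in 1 (0.00237), and all 8 chaperonin CCT genes rose (0.00281), with 2 rising in each on log2(TPM + 1); both gave adjusted p = 0.573 with an estimated correlation. The families that did not pass with all 6 libraries were mitochondrial ribosomal proteins, proteasome subunits, guanylate-binding and immunity-related (IRG) GTPases, and replication-dependent histones. Mitochondrial ribosomal protein genes gave 28 up and 6 down of 78 (camera adjusted p = 0.131). They gave 45 up without galactose replicate 2 (camera adjusted p = 0.00789), 10 down without galactose replicate 3, and 3 up and 18 down on log2(TPM + 1). Proteasome subunit genes gave 16 up and 3 down of 37 (camera adjusted p = 0.0906, or 0.0196 without galactose replicate 2). They gave 1 down without glucose replicate 3, and 2 up and 15 down on log2(TPM + 1). Guanylate-binding and IRG GTPase genes gave 8 up and 4 down of 17, or 0 up on log2(TPM + 1). Histone genes gave 1 up and 2 down of 53, or 4 up and 14 down without galactose replicate 2 and 7 up without galactose replicate 1.

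Low-level B cell transcripts were higher in galactose, such as Pax5 at 1.37 CPM in glucose and 4.57 CPM in galactose. Galactose replicate 2 alone is argued against, since 8 B cell markers were called higher without it and 7 with it. The 7 risen markers had a median log2 change of 1.699 without it and 1.674 with it. They were picked because they were called higher in these same libraries, so that median could hardly have fallen. B cells in the cultures could be a source, but the test written beforehand was met only in part, since Cd74, H2-Aa, H2-Ab1 and H2-Eb1 rose by a median of 0.873, above the bound of 0.5 but not by about as much as the risen markers. The light chain transcript Igkc, picked afterwards, moved the other way, at -0.948 (7.74 and 3.95 CPM), as did the markers Ighm (-0.83) and Bank1 (-1.13), although Ighm, at 807 CPM in glucose, is high enough to hide a small share of B cells. The source stays open; magnetic selection of naive CD4 T cells, per the labels' protocols, would remove most B cells.

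Foxp3 was higher in galactose, and no tested explanation was excluded. For a larger share of regulatory T cells, 5 of the 11 other list members fell, which met the bound set against it. Among them were Ikzf2 (9.30 to 5.01 CPM), Il10 (25.3 to 17.5 CPM) and Nrp1 (47.3 to 33.0 CPM). The other 6 rose, so the members go both ways and this explanation stays open. For stronger IL-2 and STAT5 target expression, the list's median was -0.02, with 6 of 13 members up, such as Cish (1.28), and 6 down, such as Tnfrsf9 (-1.11), and camera did not call the list at an unadjusted threshold of 0.05. That median met the bound set against it, at or below 0, by less than the members' spread, so it decides nothing; in both tests the added condition was set after the value was seen. Expression of Foxp3 within the cultured cells in response to the sugar may also contribute and was not tested.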
